A study of Arabidopsis thaliana with 28 samples.

How the data were processed

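The deposited values were signal intensities on a linear scale, 1 per probe set and array, for 28 arrays of 1 colour each. Per the submitters' processing notes, the signals were computed with the Affymetrix MAS5 method. The version of MAS5, its settings and the detection calls were not given in the sources used here. In the deposited values the mean signal after removing the lowest and highest 2% of probe sets lay between 99.2 and 99.4 on every array, so each array had been scaled by the authors to a common level. No raw image files were used here.

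From there, 64 control probe sets of 22810 were left out, and signals were analysed as log2(signal + 9.58), where 9.58 was the 25th percentile of all signals. Fold changes on this scale understate changes of transcripts with low signals. Probe sets were kept when they lay above their array's median on at least 2 of 28 arrays, which left 14806 of 22746. A linear model with 14 group means (tissue by time) was fitted to all 28 arrays in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with empirical Bayes moderation using the trend and robust options. It had 14 residual and 7.24 prior degrees of freedom. Each later time was compared with 0.25 h in the same tissue, 0.5 h and 1 h also with 24 h, and the tissues with each other. Differences between tissues in the change from 0.25 h were tested as interaction contrasts. Changes over all times were tested with moderated F tests. P-values were 2-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. Calls of at least 2-fold were counted beside these. The number of arrays limits the precision of every value. The labels do not state whether the 2 replicates of a group came from separate cultures, so p-values measure only the spread between these samples.

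Probe sets were named from the annotation tables supplied. Of 22746 probe sets, 13513 matched 1 gene, 503 several and 8730 none, and among those kept the numbers were 7914, 320 and 6572. Probe sets that matched several genes or none entered the counts and are unnamed here. Of the 13513, 13436 matched a gene identifier of the reference and 77 matched by symbol only.

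Before the data were examined, the comparisons, the filter, the pseudocount, the alternative settings other than the further gene families, 19 gene lists and the rule for naming genes were fixed. The rule took kept probe sets that match exactly 1 gene. For each time against 0.25 h it took the 3 largest rises and 2 largest falls that were called and whose arrays both lay on the same side of both 0.25 h arrays. For 0.5 h and 1 h against 24 h it took the 2 largest each way by the same criteria. For each interaction contrast it took the largest difference each way, and for shoots against roots the 3 largest each way. It also took up to 3 members per gene list and tissue by the moderated F statistic, and the reference genes. List members outside this rule that are given by name were chosen after their values were seen.

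Gene lists with at least 2 measured members were tested against all other probe sets with camera in limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 192 tests. Of these, 51 were called, and 19 were also called with an estimated correlation. The calls of the second kind were the UV-B photoreceptor list at 1 h in both tissues and against 24 h in roots, and abscisic acid and dehydration at 1 h in shoots against 0.25 h and 24 h. They were also oxidative stress and detoxification at 3 h in both tissues and at 6 h in shoots, flavonoids at 1 h and 3 h in roots, and auxin-responsive genes at 3 h and 6 h in roots. The rest were the rapid stress and touch list at 24 h in shoots, at 3 h, 6 h, 12 h and 24 h in roots, and at 0.5 h against 24 h in both tissues. For every called list the median, the mean and the test had the same sign. The other calls were lost with an estimated correlation. List tests were repeated only with an estimated correlation, quantile normalization between all arrays, replicate number as a block, or 1 array left out. The other settings named below were not applied to lists. For the 19 that were kept, the highest adjusted p under the settings tried for lists lay between 0.0225 and 0.0485. The camera values printed below used the preset correlation and are far smaller. Lists with 1 measured member and the reference genes were not tested as sets. A further 20 gene families were fixed after the files had been seen and before any model was fitted.

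The alternatives tried were no pseudocount, a pseudocount at the median signal, quantile normalization between all arrays or within each tissue, centring of arrays, no filter, a filter at the 75th percentile, separate fits per tissue, no trend and robust options, replicate number as a block, a random block of shoots and roots of the same time and number, a 2-fold minimum, and leaving out each array in turn. In a simulation on the 3 h against 0.25 h contrast, with 100 probe sets shifted per fold size, 91% of 2-fold and 98% of 4-fold changes were recovered in shoots, with 5.97% of the calls false. In roots 90% and 99% were recovered, with 4.55% false. All 10 shifted gene sets and 0 of 20 unshifted ones were called. Simulated noise was drawn separately for each probe set, so this cannot show how the list tests behave for genes that vary together. Its spread was the same in every group, while in the data the 0.25 h shoot pair, the reference there, agreed least (r = 0.978). Far fewer probe sets were shifted than were called in the data. For both reasons the share of false calls may differ there.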

Results

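Transcript levels were measured in shoots and roots of Arabidopsis thaliana (accession Col-0) after 1 exposure to UV-B, the short-wave ultraviolet part of sunlight. Per the labels, 16-day-old plants received 1.18 W/m2 for 15 min, starting 3 h into a 16 h light period. Each tissue was sampled at 7 labelled times, 0.25, 0.5, 1, 3, 6, 12 and 24 h, with 2 arrays per tissue and time and 28 arrays in all. Values were MAS5 signals, the brightness summary that Affymetrix software gives for each probe set. Median signals per array ranged from 36.7 to 39.0 in shoots and from 44.3 to 47.4 in roots. Replicate arrays correlated at Pearson's r of 0.978 (shoots at 0.25 h) to 0.994 across probe sets. Shoot and root arrays correlated at 0.395 to 0.576. The first principal component, which parted shoots from roots, held 80.6% of the variance.

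No array of untreated plants or of plants before the exposure was analysed here. The 0.25 h samples of the same tissue were therefore the reference for every later time, and changes already complete at 0.25 h do not show in these contrasts. The times from 3 h to 12 h also fell at another hour of the day than the reference did, and the labels do not say whether times count from the start or the end of the exposure. The labels do not say whether replicates were separate cultures, so p-values measured the spread between these samples, which may be technical. Of 350 members of the 19 gene lists fixed beforehand, 46 could be named and measured, so each list is described by the few members given here.

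**Figure D1:**
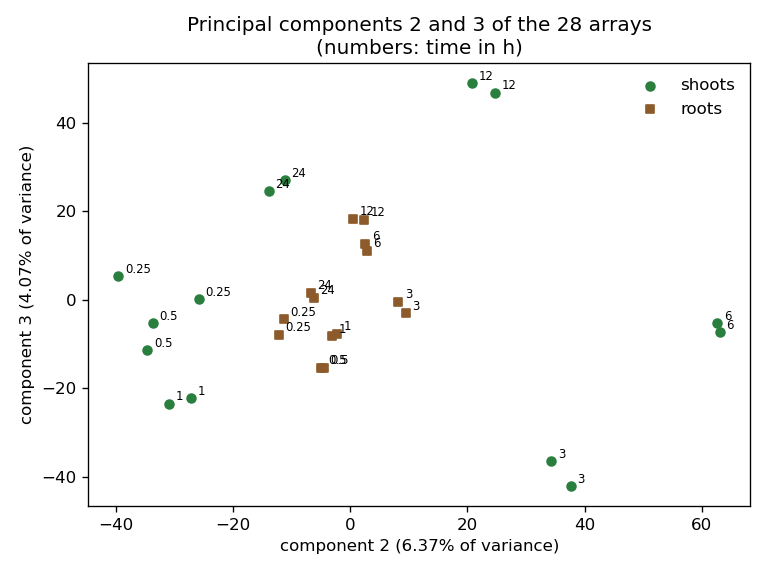
Principal components 2 (horizontal, 6.37% of the variance) and 3 (vertical, 4.07%) of the log2 signals, with 1 point per array and the labelled time in hours beside it. The shoot arrays at 3 h, 6 h and 12 h lie far from those at 0.25 h, and the root arrays lie closer together.

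The first question was which transcripts changed over time in shoots after the exposure. UGT84A1 (AT4G15480), a glucosyltransferase of hydroxycinnamic acids, rose most among named genes at 1 h, to a signal of 179 ± 41.2 (SD, n = 2). HYH (AT3G17609), a transcription factor closely related to the light regulator HY5, had risen by 1.01 ± 0.13 at 0.5 h and 1.19 ± 0.13 at 1 h (log2 ± SE, n = 2 against 2). The genes PDF1.2b (AT2G26020) and PDF1.2 (AT5G44420), which encode antifungal defensins, changed by -4.83 ± 0.33 and -4.29 ± 0.53 at 1 h (-4.22 and -3.26 without the first 0.25 h replicate). At 3 h and 6 h, genes of detoxification and of the response to oxidative stress rose together. Over all times, 12704 of 14806 probe sets changed in shoots by limma's moderated F test, and 3890 of them differed from 0.25 h by at least 2-fold at some time.

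At 0.5 h, 1143 probe sets were higher and 937 lower in shoots than at 0.25 h, of which 173 and 58 by at least 2-fold. The largest rises among named genes were those of AT5G64120 (2.49 ± 0.18; limma adjusted p = 7.14e-08), which encodes a peroxidase, XTH18 (AT4G30280, 1.96 ± 0.24), a cell wall xyloglucan endotransglucosylase, and PDF1.4 (AT1G19610, 1.94 ± 0.25). PDF1.2 and PDF1.2b already showed the largest falls, of -2.79 ± 0.53 and -2.42 ± 0.33. The PDF1.2 call was lost when shoots were fitted alone (adjusted p = 0.0610), and without the first 0.25 h replicate PDF1.2 was at -1.75 and PDF1.2b at -1.81. Genes given as largest changes against 0.25 h or 24 h were required to have both arrays beyond both reference arrays. Rankings such as rose most and fell most therefore cover only named genes that met this rule. PDF1.2 and PDF1.2b have near-identical sequences, so each probe set may detect both. Of the 3 auxin-responsive genes measured, IAA29 (AT4G32280, -1.49 ± 0.16) and GH3.3 (AT2G23170, -1.39 ± 0.33), an enzyme that conjugates auxin, fell (2 of 3 lower, 2 adjusted over the list alone; list adjusted p = 0.0888 with an estimated correlation). The GH3.3 call was lost without the first 0.25 h replicate (adjusted p = 0.0997), without the first 0.5 h replicate (0.160) and when shoots were fitted alone (0.0723), and the list's call without the second 0.25 h replicate (0.0510) or the first 0.5 h replicate (0.0727). Without the first 0.5 h replicate 938 calls were made, and 1183 when shoots were fitted alone, against 2080, and without the first 0.25 h replicate 555 were lower.

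At 1 h, 1879 probe sets were higher and 2070 lower (1994 and 1928 after centring of arrays), of which 374 and 317 by at least 2-fold. UGT84A1 rose by 4.12 ± 0.35 (limma adjusted p = 4.50e-08), followed by AT2G20142 (3.60 ± 0.19) and AT3G48640 (3.44 ± 0.40, and 2.43 without the second 0.25 h replicate). All 3 measured members of the UV-B photoreceptor pathway list rose, the third being AT1G16260 (0.48 ± 0.12, 3 adjusted over the list alone, camera adjusted p = 0.00108). The abscisic acid and dehydration list also rose in 3 of 3 members, 3 adjusted over the list alone (camera adjusted p = 4.79e-04). It held COR15A (AT2G42540, 2.92 ± 0.28) and COR15B (AT2G42530, 2.54 ± 0.25), which encode cold-induced chloroplast proteins, and the dehydrin COR47 (AT1G20440, 0.78 ± 0.14). UGT78D2 (AT5G17050), a flavonoid 3-O-glucosyltransferase, rose by 2.38 ± 0.12, and with CHIL (AT5G05270, a chalcone isomerase-like protein, 0.60 ± 0.20) 2 of the 4 measured flavonoid genes were higher, 2 adjusted over the list alone, without a camera call (adjusted p = 0.129). The CHIL call was lost without the first (0.0804) or second (0.121) 0.25 h replicate, without the first (0.0661) or second (0.162) 1 h replicate and when shoots were fitted alone (0.0938). GI (AT1G22770), a clock protein and the only measured member of the evening-phased list, rose by 2.44 ± 0.09. PDF1.2b fell to a signal of 24.4 ± 2.07. The AT1G16260 call was lost without the second 0.25 h replicate (adjusted p = 0.128) and without the second 1 h replicate (0.0678).

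At 3 h, 3489 probe sets were higher and 4071 lower in shoots, of which 1001 and 684 by at least 2-fold. AT2G04050 and AT2G04070, members of the MATE family of efflux carriers, rose by 6.48 ± 0.17 (limma adjusted p = 3.81e-17) and 5.48 ± 0.21, and AT2G23270 by 5.55 ± 0.22. All 5 measured members of the oxidative stress and detoxification list rose, 5 adjusted over the list alone (camera adjusted p = 4.35e-06). They were AT2G21640, a known marker of oxidative stress (4.64 ± 0.18), the glucosyltransferases UGT73B5 (AT2G15480, 3.40 ± 0.16) and UGT73B4 (AT2G15490, 2.87 ± 0.16), the alternative NAD(P)H dehydrogenase NDB2 (AT4G05020, 2.76 ± 0.17) and the glutathione transferase GSTU25 (AT1G17180, from a signal of 0.487 ± 0.0491 to 30.9 ± 5.39). WRKY6 (AT1G62300), a stress-related transcription factor, rose by 3.39 ± 0.14. Of the unfolded protein response list, BZIP60 (AT1G42990, 1.96 ± 0.10) and BZIP28 (AT3G10800, 0.80 ± 0.09), the membrane-bound transcription factors of that response, rose (2 of 3, 2 adjusted over the list alone; list adjusted p = 0.0831 with an estimated correlation and 0.0546 without the second 0.25 h replicate). OPCL1 (AT1G20510), an enzyme of jasmonate synthesis and the only one measured of its list, rose by 1.47 ± 0.11. PDF1.2b and PDF1.2 showed the largest falls again (-4.29 ± 0.33 and -3.72 ± 0.53, but -3.68 and -2.68 without the first 0.25 h replicate).

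The most calls were made at 6 h, with 4679 probe sets higher and 4675 lower, of which 1449 and 1297 by at least 2-fold. After centring of arrays 4129 were higher and 5378 lower, so which direction held more calls depended on the scaling. AT2G04050 (6.22 ± 0.17), AT2G04070 (5.40 ± 0.21) and AT4G34950 (5.09 ± 0.18) rose most, and AT5G48490 (-4.23 ± 0.23) and AT1G65490 (-3.64 ± 0.12) fell most. The 5 oxidative stress and detoxification genes were all still higher, 5 adjusted over the list alone, with AT2G21640 at 4.88 ± 0.18 and a signal of 1396 ± 17.0. The list's camera adjusted p was 2.30e-04, and up to 0.0485 under the other settings tried for lists. All 3 unfolded protein response genes were higher, including the co-chaperone ATERDJ3B (AT3G62600, 1.42 ± 0.12; 3 adjusted over the list alone; list adjusted p = 0.0888 with an estimated correlation). The heat shock list had both members higher, AT5G48570 by 2.86 ± 0.17 and AT5G37670 by 1.02 ± 0.19 (2 adjusted over the list alone), without a camera call (adjusted p = 0.0987). All 4 flavonoid genes fell, 4 adjusted over the list alone. They were CHIL (-1.78 ± 0.20), UGT78D2 (-1.47 ± 0.12), the dihydroflavonol reductase DFR (AT5G42800, -1.45 ± 0.42) and UGT78D1 (AT1G30530, -1.03 ± 0.21), and the list's adjusted p was 0.291 with an estimated correlation. The flavonoid list's call was also lost without the first (0.0549) or the second (0.0510) 0.25 h replicate. All 5 photosynthesis genes were lower, 5 adjusted over the list alone, with PSAN (AT5G64040, photosystem I) at -1.02 ± 0.12, without a camera call (adjusted p = 0.0659). Under quantile normalization between all arrays LHCB4.1 (AT5G01530), LHCB4.2 (AT3G08940), RCA (AT2G39730) and the reference gene GAPC2 (AT1G13440, -0.59 ± 0.11) were no longer called (adjusted p = 0.831, 0.0797, 0.494 and 0.281). Within each tissue this held for LHCB4.1 (0.838), RCA (0.463) and GAPC2 (0.184). LHCB4.1 also lost its call without the first 0.25 h replicate (0.127) or the second 6 h replicate (0.160).

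At 12 h, 3780 probe sets were higher and 2996 lower, of which 565 and 844 by at least 2-fold. AT4G34950 (5.75 ± 0.18), AT2G23910 (3.90 ± 0.18) and AT1G07050 (3.71 ± 0.18) rose most, and AT4G27280 (-5.00 ± 0.17) and STZ (AT1G27730, -4.72 ± 0.14), a zinc finger transcription factor also called ZAT10, fell most. PDF1.2b was back at a signal of 1399 ± 382, against 1041 ± 591 at 0.25 h. The rapid stress and touch list had 3 of 4 members lower and 1 higher, and the same counts adjusted over the list alone (list adjusted p = 0.105 with an estimated correlation). IAA29 (-1.85 ± 0.16), GH3.3 (-1.25 ± 0.33) and WES1 (AT4G27260, another auxin-conjugating enzyme, -1.82 ± 0.14) were all lower, 3 adjusted over the list alone (list adjusted p = 0.0587 with an estimated correlation). GH3.3 lost its call without the first 0.25 h replicate (adjusted p = 0.0740) and without the second 12 h replicate (0.102).

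At 24 h, 2135 probe sets were higher and 1684 lower than at 0.25 h, of which 166 and 321 by at least 2-fold. STZ fell most, from a signal of 1568 ± 33.0 to 42.4 ± 1.03 (-4.92 ± 0.14; limma adjusted p = 1.39e-16), followed by AT4G29780 (-4.12 ± 0.16). With it fell WRKY53 (AT4G23810), a senescence-related transcription factor, from a signal of 252 ± 39.5 to 17.7 ± 9.59, and the calmodulin-like CML38 (AT1G76650, -3.25 ± 0.15), while WRKY6 was higher (0.74 ± 0.14). The rapid stress and touch list was lower in 3 of 4 members and higher in 1, with the same counts adjusted over the list alone (camera adjusted p = 8.47e-05). AT2G23910 (3.45 ± 0.18), AT3G47480 (2.17 ± 0.44) and AT3G28510 (1.99 ± 0.36) rose most, though without the second 0.25 h replicate AT3G47480 was at 1.04 and AT3G28510 at 1.06. AT2G21640 was still higher, by 1.63 ± 0.18. Without the second 24 h replicate 2464 calls were left of 3819.

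**Figure D2:**
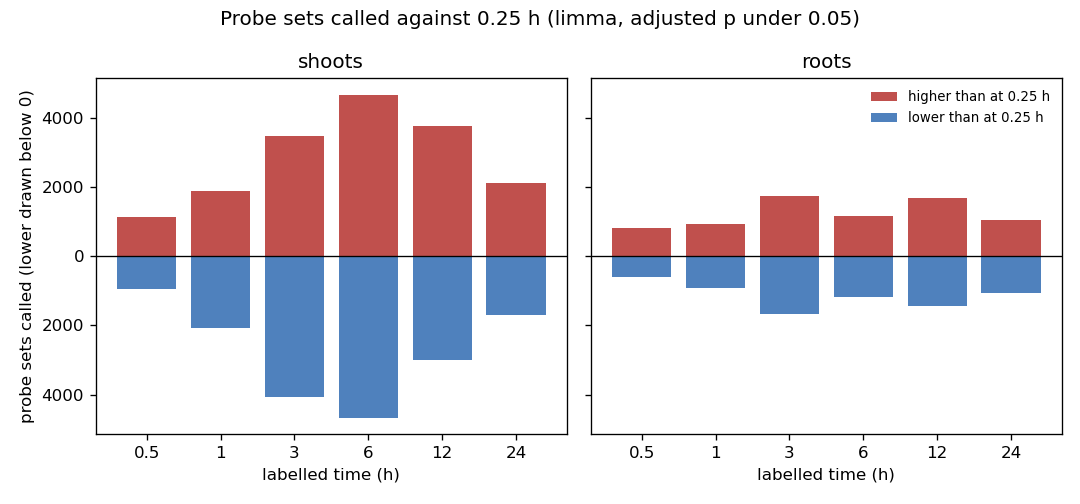
Number of probe sets called higher (drawn upwards) and lower (drawn downwards) than at 0.25 h in the same tissue, at each later labelled time in hours (limma, n = 2 arrays per time). Shoots reached 4679 and 4675 at 6 h, and roots had at most 1756 and 1679, at 3 h.

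The same question was asked of roots. UGT84A1 rose there too, from a signal of 6.31 ± 0.136 at 0.25 h to 437 ± 18.9 at 1 h (SD, n = 2 each). Genes of flavonoid synthesis were higher at 1 h and 3 h than at 0.25 h, with UGT78D1, a flavonol rhamnosyltransferase, at a signal of 195 ± 27.4 at 3 h against 22.1 ± 5.67. The 5 oxidative stress and detoxification genes were higher at 3 h, though UGT73B4 was not called there without a pseudocount (adjusted p = 0.107). STZ, WRKY53 and CML38 fell from 1 h on, and GH3.3 and WES1 fell at 3 h. Over all times 7914 of 14806 probe sets changed in roots by limma's moderated F test, 1144 of them by at least 2-fold at some time.

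At 0.5 h, 830 probe sets were higher and 612 lower in roots, of which 137 and 94 by at least 2-fold. OCT1 (AT1G73220), an organic cation transporter, rose by 2.09 ± 0.19 and AT4G01390 by 1.98 ± 0.26. PR-1-LIKE (AT2G19990, -2.62 ± 0.15; limma adjusted p = 8.82e-10) and AT4G33560 (-2.30 ± 0.28) fell most. The largest rise, of AT5G26270 (3.44 ± 0.96), lost its call when any 1 of the 4 arrays was left out (adjusted p from 0.0950 to 0.172). The oxidative stress and detoxification list had 3 of 5 members higher, 4 adjusted over the list alone (list adjusted p = 0.0523 with an estimated correlation). The calls of 2 of these, GSTU25 and UGT73B4, were lost without a pseudocount (adjusted p = 0.258 and 0.429), without the first 0.25 h replicate (0.0893 and 0.212) and without the first 0.5 h replicate (0.0788 and 0.106), and that of UGT73B4 also without the second 0.5 h replicate (0.0902). In the photosynthesis list, RCA (AT2G39730, Rubisco activase, 0.53 ± 0.14) and PSAN (0.48 ± 0.12) were higher, 2 of 5, 2 adjusted over the list alone (list adjusted p = 0.455 with an estimated correlation). Of 205 abundant probe sets typical of shoots, 119 were higher in both 0.5 h root arrays than in both 0.25 h ones, with a median log2 change of 0.26. The RCA call was lost without the first (0.130) or second (0.0518) 0.25 h replicate or the first 0.5 h replicate (0.198), the PSAN call without the first 0.25 h (0.114) or first 0.5 h replicate (0.157), and the list's call in 13 omissions of 1 array (highest 0.350). The number of calls fell from 1442 to between 626 and 835 when any 1 of the 4 arrays was left out, and it was 2221 when roots were fitted alone.

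At 1 h, 932 probe sets were higher and 931 lower, of which 183 and 158 by at least 2-fold. UGT84A1 (4.81 ± 0.35; limma adjusted p = 1.34e-08), AT2G22590 (3.66 ± 0.22) and AT2G41730 (3.20 ± 0.19) rose most, and WRKY53 (-2.48 ± 0.20) and AT3G61930 (-2.38 ± 0.25) fell most. HYH rose by 1.52 ± 0.13. In the UV-B photoreceptor pathway list 2 of 3 measured members were higher, 2 adjusted over the list alone (camera adjusted p = 7.88e-04). UGT78D2 (2.12 ± 0.12), UGT78D1 (2.09 ± 0.21) and CHIL (1.51 ± 0.20) rose, 3 of the 4 flavonoid genes, 3 adjusted over the list alone (camera adjusted p = 7.06e-06). STZ (-1.41 ± 0.14) and CML38 (-1.01 ± 0.15) fell with WRKY53, 3 lower and 1 higher of 4 in the rapid stress and touch list, the same adjusted over the list alone (list adjusted p = 0.0774 with an estimated correlation). The higher one was WRKY6, whose call was lost without a pseudocount (adjusted p = 0.122), without the second 0.25 h replicate (0.0562) and without the first (0.0600) or second (0.0585) 1 h replicate. Calls numbered 1863, but 1220 without the first 0.25 h replicate, 1186 without the first and 1077 without the second 1 h replicate.

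At 3 h, 1756 probe sets were higher and 1679 lower in roots, of which 256 and 281 by at least 2-fold. AT2G41730 (4.74 ± 0.19), AT2G23910 (4.22 ± 0.18) and AT5G43450 (4.17 ± 0.16; limma adjusted p = 5.14e-14) rose most, and AT5G52760 (-3.56 ± 0.25) and AT2G25510 (-2.90 ± 0.15) fell most. The 5 oxidative stress and detoxification genes were higher, 5 adjusted over the list alone (camera adjusted p = 5.07e-07), AT2G21640 by 3.63 ± 0.18 and GSTU25 by 2.29 ± 0.15, and the UGT73B4 call was lost without a pseudocount (adjusted p = 0.107). UGT78D1 (2.70 ± 0.21), CHIL (2.43 ± 0.20) and UGT78D2 (1.27 ± 0.12) remained higher, 3 of 4, 3 adjusted over the list alone. The list's camera adjusted p was 7.34e-05, and up to 0.0485 under the other settings tried for lists. DFR was at 0.55 ± 0.42 (limma adjusted p = 0.387). GH3.3 (-2.88 ± 0.33) and WES1 (-1.68 ± 0.14) fell, 2 of 3 auxin-responsive genes, 2 adjusted over the list alone (camera adjusted p = 0.00190). The cell division kinases AUR1 (AT4G32830, -0.74 ± 0.16) and AUR2 (AT2G25880, -0.53 ± 0.19) were lower, 2 of 2, 2 adjusted over the list alone, without a camera call (adjusted p = 0.129). STZ, WRKY53 and CML38 were lower, 3 of 4 rapid stress and touch genes, 3 adjusted over the list alone. That list's camera adjusted p was 2.74e-04, and up to 0.0485 under the other settings tried for lists. The AUR2 call was lost without a pseudocount (adjusted p = 0.0866), without the filter (0.0634), with replicate number as a block (0.0503), without limma's trend and robust options (0.0501), and without the first (0.0530) or second (0.288) 0.25 h or the second 3 h replicate (0.398). Calls numbered 3435, but 2136 without the first 0.25 h replicate, 2169 without the first and 1857 without the second 3 h replicate.

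At 6 h, 1166 probe sets were higher and 1170 lower (1202 and 1158 after centring), of which 76 and 221 by at least 2-fold. The defensin-family gene PDF2.1 (AT2G02120, 3.01 ± 0.18; limma adjusted p = 1.10e-10), AT1G11210 (2.60 ± 0.24) and the cold-regulated COR27 (AT5G42900, 2.54 ± 0.18) rose most, and AT5G52760 (-3.11 ± 0.25) and AT4G29780 (-2.89 ± 0.16) fell most. STZ, WRKY53 and CML38 were lower, 3 of 4 in the rapid stress and touch list, 3 adjusted over the list alone (camera adjusted p = 4.35e-06). Of the auxin-responsive list, GH3.3 (-2.01 ± 0.33) and WES1 (-1.29 ± 0.14) were lower, 2 of 3, and 3 adjusted over the list alone (camera adjusted p = 0.00197). The number of calls fell from 2336 to between 1127 and 1487 when any 1 of the 4 arrays was left out.

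At 12 h, 1698 probe sets were higher and 1450 lower, of which 100 and 330 by at least 2-fold. AT2G23910 (2.88 ± 0.18), UGT84A1 (2.04 ± 0.35) and AT2G22590 (1.87 ± 0.22) rose most, and AT1G73120 (-3.91 ± 0.38) and STZ (-3.27 ± 0.14; limma adjusted p = 2.25e-13) fell most. The rapid stress and touch list was lower in 3 of 4 members, and in 4 adjusted over the list alone (camera adjusted p = 5.07e-07). Of the flavonoid genes, CHIL (1.33 ± 0.20), UGT78D1 and UGT78D2 were higher, 3 of 4, and 4 adjusted over the list alone (list adjusted p = 0.214 with an estimated correlation). Calls numbered 3148, but 1646 without the first 0.25 h replicate and 2073 without the second 12 h replicate, and without the first 12 h replicate 1110 were higher. UGT78D2 lost its call without the first (0.104) or second (0.120) 0.25 h or the first 12 h replicate (0.268), and UGT78D1 without the second 0.25 h (0.124) or the first 12 h replicate (0.0907).

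At 24 h, 1048 probe sets were higher and 1075 lower in roots (1203 and 952 after centring), of which 136 and 234 by at least 2-fold. AT1G26380 (2.99 ± 0.44) and AT1G26390 (2.56 ± 0.59), which encode berberine-bridge-enzyme-like oxidases, and AT2G38870 (2.46 ± 0.29) rose most. AT5G52760, from a signal of 147 ± 4.78 to 6.27 ± 1.13, and AT2G30670 (-3.28 ± 0.15; limma adjusted p = 6.19e-12) fell most. STZ (-2.87 ± 0.14), CML38 (-2.15 ± 0.15) and WRKY53 (-1.99 ± 0.20) were lower, 3 of 4 rapid stress and touch genes, 3 adjusted over the list alone (camera adjusted p = 4.35e-06). The AT1G26390 call was lost without the second 0.25 h replicate (adjusted p = 0.0542). The number of calls fell from 2123 to between 1027 and 1397 when any 1 of the 4 arrays was left out, and it was 3268 when roots were fitted alone.

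**Figure D3:**
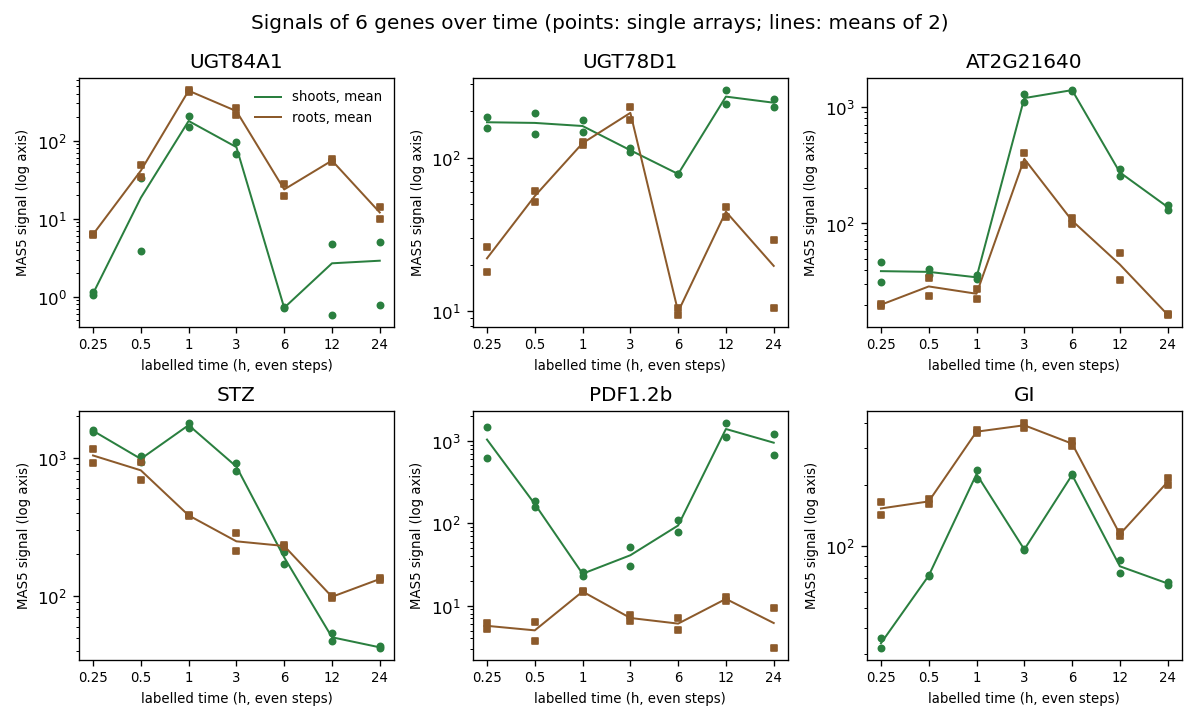
MAS5 signals (log axis) of UGT84A1, UGT78D1, AT2G21640, STZ, PDF1.2b and GI at the 7 labelled times (h, drawn at even steps) in shoots and roots, with points for single arrays and lines for means of 2. UGT84A1 peaked at 1 h in both tissues, at 179 in shoots and 437 in roots.

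The 0.5 h and 1 h samples were also set against those of 24 h, which fell at nearly the same hour of the light period. In shoots STZ was higher at 0.5 h (4.25 ± 0.14) and at 1 h (5.06 ± 0.14; limma adjusted p = 5.27e-17) than at 24 h, and AT1G19020 was higher by 4.29 ± 0.12 and 4.64 ± 0.12. At 1 h, UGT84A1 was higher than at 24 h by 3.92 ± 0.35 in shoots and 4.37 ± 0.35 in roots. All 4 rapid stress and touch genes were higher at 0.5 h than at 24 h in shoots and in roots, 4 adjusted over the list alone in each (camera adjusted p = 1.86e-08 and 4.35e-06), though the WRKY6 call in roots was lost without a pseudocount (adjusted p = 0.0621). The abscisic acid and dehydration list was higher at 1 h in shoots in 3 of 3 members, 3 adjusted over the list alone (camera adjusted p = 0.00113). In roots the UV-B photoreceptor pathway list was higher at 1 h in 3 of 3 members, 3 adjusted over the list alone (camera adjusted p = 2.07e-04).

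Among the largest differences from 24 h in shoots, AT2G23910 (-3.04 ± 0.18) was lower at 0.5 h and PDF1.2b (-4.77 ± 0.33) at 1 h. The gene the tables call CHI (AT2G43570), which encodes a chitinase-family protein, was lower at 0.5 h (-2.82 ± 0.70) and 1 h (-4.13 ± 0.70). In roots AT5G52760 (a signal of 146 ± 0.430 against 6.27 ± 1.13) and the expansin-like EXLA3 (AT3G45960, 2.89 ± 0.15) were higher at 0.5 h, and AT2G22590 (3.27 ± 0.22) at 1 h. The cytochrome P450 gene CYP718 (AT2G42850) was lower at both times (-2.87 ± 0.18 and -2.86 ± 0.18), AT4G10270 at 0.5 h (-2.55 ± 0.20) and AT1G26390 at 1 h (-3.53 ± 0.59). In shoots 1813 probe sets were higher and 2361 lower at 0.5 h, and 2534 and 3355 at 1 h. Without the first 24 h replicate 1511 were lower at 0.5 h. In roots these numbers were 1640 and 1445 at 0.5 h, and 1647 and 1518 at 1 h, but 1453 and 1686, and 1501 and 1633, after centring, so the larger direction turned. The CHI call at 0.5 h was lost when shoots were fitted alone (adjusted p = 0.0803). Root calls were 1928 and 1764 without the first and second 0.5 h replicate and 1501 without the second 24 h replicate, against 3085, and 2012, 1846 and 1800 likewise at 1 h, against 3165.

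Whether shoots and roots followed different courses was tested by the interaction of tissue and time. UGT78D1 rose by 2.70 ± 0.21 in roots at 3 h and was at -0.56 ± 0.21 in shoots, a difference of -3.26 ± 0.30 (limma adjusted p = 6.54e-08). The shoot value was not called without a pseudocount (0.110), without the second 0.25 h replicate (0.171) or without the first (0.131) or second (0.0739) 3 h replicate. CHIL differed by -2.24 ± 0.29 and UGT78D2 by -1.87 ± 0.17 at that time, shoots minus roots. AT2G04050 rose by 6.22 ± 0.17 in shoots at 6 h and was at 0.81 ± 0.17 in roots, a difference of 5.40 ± 0.23 (adjusted p = 1.01e-12). The fall of PDF1.2b in shoots could not be set against roots, as its root signal of 5.70 ± 0.764 at 0.25 h lay under the pseudocount of 9.58. The course differed for 10686 of 14806 probe sets by limma's moderated F test.

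The number of probe sets whose change from 0.25 h differed between tissues was 906 at 0.5 h, 2106 at 1 h, 5352 at 3 h, 7216 at 6 h, 3927 at 12 h and 1833 at 24 h. At 3 h, 828 probe sets were higher in both tissues and 775 lower in both, where independent lists of those sizes would share 414 and 462. Opposite calls at 3 h numbered 199 and 253, where 396 and 483 would be shared by independent lists. AT3G48640 showed the largest positive difference at 1 h (4.09 ± 0.56) and at 3 h (5.70 ± 0.56), though these were 3.08 and 4.69 without the second 0.25 h shoot replicate. The count at 0.5 h was 534 without the first 0.25 h root replicate, 487 without the first 0.5 h shoot replicate, and 549 and 386 without the first and second 0.5 h root replicate. The count at 1 h was 1340 without the second 1 h root replicate.

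Shoots and roots were compared over all 7 times to check the tissue labels. AT1G23130 (7.67 ± 0.05), ECS1 (AT1G31580, 7.35 ± 0.09) and AT1G67865 (6.63 ± 0.07) were the named genes highest in shoots. AT4G15390 (-6.85 ± 0.05), AT4G30170 (-6.57 ± 0.06), which encodes a peroxidase, and the osmotin OSM34 (AT4G11650, -6.16 ± 0.15) were highest in roots. All 5 photosynthesis genes were higher in shoots, from LHCB4.3 (AT2G40100, 4.19 ± 0.06) to LHCB4.2 (AT3G08940, 6.14 ± 0.07), both antenna proteins of photosystem II. The root markers PYK10 (AT3G09260, -2.83 ± 0.11), a beta-glucosidase, and the root hair expansins EXPA7 (AT1G12560, -1.80 ± 0.10) and EXPA18 (AT1G62980, -1.70 ± 0.06) were all higher in roots. In all 4646 probe sets were higher and 8875 lower in shoots, 2407 and 2622 by at least 2-fold (limma, 14 arrays each). The median log2 difference over all probe sets was -0.28. Calls were 5383 higher and 7917 lower under quantile normalization between all arrays, and 5575 and 7579 after centring. The excess of lower calls thus depended in part on the scaling.

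In the lists with 1 measured member, SAG101 (AT5G14930), a protein of salicylate-related defence, was lower in roots at 24 h (-1.41 ± 0.22) and higher in shoots at 6 h (0.84 ± 0.22). The replication gene PRL (AT4G02060) was lower in shoots at 24 h (-0.57 ± 0.15) and at -0.31 ± 0.15 in roots (adjusted p = 0.181). Both shoot calls were lost without the second 0.25 h replicate (0.0744 and 0.0762), and that of PRL without the second 24 h replicate (0.136). PYK10 fell in shoots at 12 h (-1.30 ± 0.29), without a camera call for the 3 root markers (adjusted p = 0.479). In the general phenylpropanoid list, ALDH2C4 (AT3G24503), an aldehyde dehydrogenase of sinapate synthesis, rose in shoots at 12 h (1.47 ± 0.10) while the hydroxycinnamoyltransferase HCT (AT5G48930) fell (-1.01 ± 0.09), 1 each way, the same adjusted over the list alone (camera adjusted p = 0.968). All 3 measured reference genes changed over time in shoots and 0 in roots by limma's moderated F test. AT4G34270 (adjusted p = 0.0175 in shoots) was not called against 0.25 h at any single time. It was at -0.29 ± 0.11 in shoots at 1 h against 24 h, a call (adjusted p = 0.0475) lost under 8 settings that kept all arrays (adjusted p up to 0.113) and without the second 1 h (0.474) or second 24 h replicate (0.402). PEX4 (AT5G25760) was higher in shoots at 1 h (0.44 ± 0.12), a call lost without the first 0.25 h replicate (adjusted p = 0.339), without the second 1 h replicate (0.0733) and when shoots were fitted alone (0.0559). At 3 h and 24 h, where it was not called, it was called lower without the first 0.25 h replicate (adjusted p = 0.0464 and 0.0466) and higher without the second (0.35 and 0.31 on the log2 scale). No member of the lists for DNA damage and for morning-phased clock genes was named by the tables used, and these lists were not analysed here.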

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

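The interaction tests were planned, and the members of the flavonoid list are given here for 3 h, a time chosen after its values were seen. The change from 0.25 h differed between shoots and roots, by limma's interaction contrasts, for 906 probe sets at 0.5 h, 2106 at 1 h, 5352 at 3 h, 7216 at 6 h, 3927 at 12 h and 1833 at 24 h. The whole course differed for 10686.

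AT5G64120, a peroxidase gene, differed at 0.5 h by 3.25 on the log2 scale, shoots minus roots (2.49 in shoots, -0.76 in roots). PDF1.2 differed at 0.5 h by -2.64 (adjusted p = 0.0470), a call lost without a pseudocount, without the filter and without any 1 of 7 of the 8 arrays (adjusted p up to 0.126), and its value was -1.60 without the first 0.25 h shoot replicate. AT3G48640 differed by 4.09 at 1 h and 5.70 at 3 h (3.08 and 4.69 without the second 0.25 h shoot replicate). PDF1.2b differed by -5.50 at 1 h and -4.41 at 3 h (-4.90 and -3.81 without the first 0.25 h shoot replicate), but its root signal of 5.70 ± 0.764 at 0.25 h lay under the pseudocount of 9.58, so a fall in roots could not have been measured. At 6 h AT2G04050 differed by 5.40 (6.22 in shoots, 0.81 in roots) and AT5G48490 by -4.02. At 12 h AT4G34950 differed by 4.17 and AT1G66100 by -3.84, with the same limit for AT1G66100 (a root signal of 7.19 ± 1.85 at 0.25 h). AT3G28510 differed at 24 h by 4.88, with 1.99 in shoots and -2.89 in roots, and without the second 0.25 h shoot replicate by 3.95, with 1.06 in shoots. AT4G37290 differed at 24 h by -4.16.

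Among flavonoid genes at 3 h, UGT78D1 differed by -3.26, CHIL by -2.24 and UGT78D2 by -1.87, shoots minus roots. DFR differed by -1.57 (adjusted p = 0.0467), a call lost with a pseudocount at the median signal, without the filter and without any 1 of 7 of the 8 arrays (adjusted p up to 0.222, at -1.02, without the second 3 h root replicate).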

How the results depend on the processing

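The list families fixed later are the only alternative here chosen after seeing the data. With 2 arrays per group, leaving 1 out leaves a lone array that is assumed to vary like the other groups. Signals near the background limit what can be seen of weakly expressed genes, and no detection calls were used here. Quantile normalization, centring, either pseudocount and no filter left every total number of probe sets called within 1.5 times its value. So did no trend and robust options, and replicate number as a block. By direction, 388 probe sets were lower in roots at 0.5 h without a pseudocount, against 612, and 333 higher for the interaction at 0.5 h, against 500. Under both quantile normalizations and centring the larger direction turned for shoots at 6 h, roots at 6 h and 24 h, roots at 0.5 h and 1 h against 24 h, and the interaction at 6 h and 24 h. Under some of them it turned for shoots at 1 h and the interaction at 1 h and 12 h. Replicate numbers did not pair arrays across groups (r of residuals from -0.22 to 0.22 over 91 pairs of groups). A random block of tissue pairs gave a correlation of 0.00164 and left 8 of 8 counts within that range.

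Separate fits per tissue gave 1183 calls for shoots at 0.5 h, 2221 for roots at 0.5 h and 3268 for roots at 24 h. They gave 1768 higher in roots at 6 h against 1166. Log2 changes are the same in both fits, so only the spread estimate and its degrees of freedom differ. Replicates differed at least 2-fold for 1.60% and 1.19% of probe sets in shoots at 0.25 h and 0.5 h, and 0.04% at 12 h. In roots the highest shares were 0.65% at 12 h and 0.14% at 6 h. Counts therefore depend on the spread that the main model shares between tissues, and the cause was not tested further. The filter at the 75th percentile gave 8424 for shoots over time and 8568 for shoots against roots, as fewer probe sets were tested. With an estimated correlation 19 list calls were left of 51. Called lists numbered 40 to 51 with 1 array left out and 48 under quantile normalization, and 70 of 320 tests were called for the families fixed later.

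A 2-fold minimum lowers counts by construction. It gave 3890 for shoots over time, 1144 for roots and 4029 for the differing course. Against 0.25 h, at 0.5, 1, 3, 6, 12 and 24 h, it gave 231, 691, 1685, 2746, 1409 and 487 in shoots, 231, 341, 537, 297, 430 and 370 in roots, and 317, 644, 1763, 2572, 1209 and 619 for the interaction. Against 24 h, at 0.5 h and 1 h, it gave 662 and 1067 in shoots and 468 and 475 in roots. Shoots against roots gave 5029.

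Leaving out 1 array lowers the residual degrees of freedom and sets 1 array against 2, which raises the standard error. Calls can therefore be lost while the estimate hardly moves. BZIP28 in roots at 0.5 h against 24 h lost its call at -0.26 without the first 0.5 h replicate, against -0.27. Otherwise the cause was not tested. Counts in shoots then ranged from 938 to 2320 at 0.5 h and from 2464 to 3304 at 24 h. In roots they ranged from 626 to 835 at 0.5 h, 1077 to 1349 at 1 h, 1857 to 2428 at 3 h, 1127 to 1487 at 6 h, 1646 to 2432 at 12 h and 1027 to 1397 at 24 h. Against 24 h in roots they ranged from 1501 to 2311 at 0.5 h and from 1800 to 2238 at 1 h. The interaction ranged from 386 to 1271 at 0.5 h and from 1340 to 2138 at 1 h.

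Of 643 results for named genes 346 were called, of which 58 lost the call under another setting that kept all arrays and 90 on leaving out an array. The falls of 2 called genes at 12 h in shoots changed sign. RCA was at 0.0107 under quantile normalization between all arrays and 0.00903 within each tissue, and GAPC2 at 0.0437 and 0.0469. With 1 array left out PEX4, which had not been called, ranged from -0.28 to 0.31 at 24 h and from -0.25 to 0.35 at 3 h in shoots, and the lowest values, without the first 0.25 h replicate, were called (adjusted p = 0.0466 and 0.0464). The cause was not tested.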

Other observations

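The gene families in the next paragraph were fixed after the files had been seen, and the tests of the rapid stress and touch list at 24 h and of shoots at 6 h were chosen after those results were seen.

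Transcripts of small heat shock proteins and chaperones were higher in shoots at 3 h in 11 of 15 members and lower in 1 (list adjusted p = 0.156 with an estimated correlation), and at 6 h in 14 and lower in 1 (adjusted p = 0.156). Of 17 expansins and xyloglucan endotransglucosylases, which loosen cell walls, 14 were lower in shoots at 6 h (adjusted p = 0.225). Of 63 plastid-encoded transcripts, 22 were higher at 0.5 h in shoots (camera adjusted p = 0.401) and 25 in roots (0.291). In both, 0 were lower. Whether RNA from shoots in the 0.5 h root samples, discussed below, raised the 25 was not tested. At 6 h in shoots 36 were lower and 1 higher (camera adjusted p = 0.622). Of 10 autophagy genes, 9 were lower at 1 h than at 24 h in shoots (adjusted p = 0.156) and 7 in roots (adjusted p = 0.225). All of these p-values used an estimated correlation. Over these families 70 of 320 camera tests were called, and 0 were called with an estimated correlation.

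A hypothesis was that the large rises in shoots at 3 h, among them AT2G04050, AT2G04070 and AT2G21640, were part of the published group of genes induced when mitochondria fail. The 6 members seen when the group was written down had a median log2 change of 5.15. The 6 members not looked at before were all higher, with a median of 1.92 (camera p = 3.45e-06, and 0.00319 with an estimated correlation). This is consistent with a shared response of that group, which remains a hypothesis, and mitochondria were not measured.

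A second hypothesis was that the published core genes of low oxygen fell together in roots at 0.5 h. The 8 members seen beforehand had a median of -2.02, and 7 were lower. Among 16 members not looked at before, 4 were lower and 2 higher, with a median of -0.29 (camera p = 0.0113, and 0.182 with an estimated correlation). The prediction of a median under -0.5 was not met, and the question stays open.

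The rapid stress and touch list was lower at 24 h than at 0.25 h in both tissues, with medians of -2.07 in roots and -3.27 in shoots. By their labels both samples fell at nearly the same hour, and this design, not a separate test, argues against time of day. Array scaling is argued against by medians of -2.12 in roots and -3.24 in shoots under quantile normalization between all arrays, and -2.05 in roots after centring. Handling or a light change at the exposure could give the same course without UV-B, and 0 arrays of plants handled without UV-B were analysed here. Such handling and UV-B itself cannot be told apart for that list.

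Shoots at 6 h held the most calls. Array scaling is argued against, since 9000 calls were left under quantile normalization between all arrays, with at most 7351 at any other time, and 9507 after centring. The 6 h pair of arrays correlated at r = 0.991, near the median of 14 pairs, which decides nothing about poorly agreeing arrays, though leaving out either 6 h array left 8270 or 8340 calls. The margin of 0.00289 used to judge that r was set after it was seen. Time of day could contribute, and with 0 arrays of untreated shoots analysed here it cannot be told apart from the treatment.

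Photosynthesis transcripts were higher in roots at 0.5 h in 2 of 5 members. RNA from shoots in those samples could raise them, and would raise nearly all abundant shoot transcripts with them. Of 205 such probe sets, chosen without the root arrays at 0.25 h and 0.5 h, 58.0% were higher in both arrays and 6.83% lower, where chance gives 16.7%, with a median of 0.26 against 0.32 for the photosynthesis list. The bound set beforehand for excluding shoot RNA was 60%, and the value lay under it by less than its binomial error of 3.45 points. That margin was applied after the value was seen. It treats probe sets read on the same arrays as independent, so it is likely too small and cannot decide the question. The 16.7% holds for a single probe set, and a shift shared within an array can move many together. Shoot RNA and a change in the roots cannot be told apart for these genes.

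For shoots against roots, 1 of 100 splits of the 28 arrays into 14 and 14, the real one, gave as many calls. It gave 12001 in a model with 2 groups, and the highest of the others gave 7384. The first principal component already parted shoots from roots, and every other split mixed the tissues. The count therefore restates that separation and adds no separate support.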
